A study of Caenorhabditis elegans with 4 samples.

How the data were processed

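The series holds 4 libraries from mixed-sex wild-type N2 worms of Caenorhabditis elegans at the L3 larval stage, grown at 20 °C: 2 chromatin immunoprecipitation (ChIP) libraries made with a rabbit polyclonal antibody against NURF-1, and 2 libraries of input DNA. Per the labels' protocols, frozen ground worms were crosslinked for 20 minutes with the long-arm crosslinker EGS and for a further 10 minutes with EGS plus formaldehyde. Chromatin was sonicated, and the libraries were size-selected on a gel and sequenced on Illumina instruments. The labels do not say whether the replicates came from separate worm cultures, so the spread between them may be technical.

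Reads were aligned with BWA to ce10, per the submitters' processing notes, and the coordinates are on WormBase WS220, per the file headers. Peaks were called with MACS, per the source column of the deposited files. The version, the thresholds, the use of the input libraries as background and any filter are not given in the sources used here. The authors deposited 3 peak lists: 1 for each ChIP replicate and 1 for the whole series. Each deposited peak has a first base, a last base and a score. The scale of the deposited score is not stated. Score levels were compared only between peaks of the same list, since scores of different lists may not be comparable. The correlation between lists pairs scores without comparing their levels. No list holds read counts, so the sequencing depth behind a peak is unknown. Intervals on shares of peaks cover counting error only. Peak or coverage values of the input libraries were not analysed here, so no value could be set against input.

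Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The length of each of the 6 nuclear chromosomes was taken as the last base of its last peak, which was the same in all 3 lists. Mitochondrial peaks were kept apart. Peaks of the 2 replicates counted as shared when they overlapped by at least 1 bp. Overlapping peaks of both replicates were merged into regions, and each region was classed as found in both replicates or in 1 replicate alone. Chance overlap came from 10000 circular shifts of the replicate 2 list within each chromosome, which keep peak widths and spacing (one-sided permutation test). Median scores of shared and unshared peaks were compared with a two-sided permutation test of 100000 resamples over peaks. Peaks are not replicates of the experiment, so such a p-value describes these lists only. Chromosome densities were compared with an exact permutation test of X against the 5 autosomes, which cannot go below p = 0.167. The share of region midpoints in the middle 33.3% of each chromosome was compared with that share by an exact sign-flip test over 6 chromosomes, which cannot go below p = 0.0312. Spacing was compared with 10000 random placements of each region on its chromosome, and with 10000 placements within its own window of 100 kb, which keep broad differences in density. Placed regions may overlap and then count as neighbours. Real regions cannot overlap, so the chance shares are raised, and a share close to chance does not decide the question. Shares carry 95% Wilson intervals. With 2 ChIP lists no test between replicates was possible.

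The comparison of X peaks with other peaks of like score was added after the data were seen. It drew X labels at random within 50 score strata, 100000 times (two-sided permutation test). Both spacing comparisons, the densities and the shares found by score group, the centre comparison on the 5 autosomes alone, the counts in windows and the test of chromosome ends were also added then. The other tests, the gene lists and the rule for named regions were fixed before the data were examined. By that rule, the text draws on the 20 regions in both replicates with the best mean score rank over the replicate lists, and on the 3 best-scored regions of each replicate alone; other regions are said to have been chosen later. The rule also named members of the NURF complex and of 28 fixed gene lists. These gene lists, and the planned classes of promoter, exon, intron and intergenic sequence, were not analysed. The gene table at hand is on another genome build (WBcel235), builds were not mixed, and regions are therefore given by WS220 coordinates without gene names.

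The methods were tested on simulated data. With 60% of the 4850 nuclear replicate 1 peaks planted in a simulated second list, and 62.0% expected to overlap once chance was added, 62.1% were found shared. For the comparison of X peaks at like score, the permutation test called 3.9% of 1000 simulations without an X effect at a threshold of 0.05, and 99.8% of those in which 20% of the shared X peaks were removed. Simulated peaks were found independently of each other, as the test assumes, so dependence between near peaks was not covered. For spacing within windows, the permutation test called 2 of 20 simulations without short-range clustering, and all 20 in which 10% of regions were given a near neighbour. Their regions were placed by the rule of the test, overlaps included, so these simulations could not show a bias from that rule. Alternatives covered the overlap required, the score threshold, equal list lengths, random placement, peak width, the replicate or list used, bases in place of regions, and the definition of the chromosome centre.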

Results

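NURF-1 is the worm homologue of BPTF, the large subunit of the nucleosome remodelling factor NURF, a chromatin complex built around an ISWI-class ATPase. Its binding was profiled by ChIP sequencing in L3 larvae of the wild-type strain N2, in 2 ChIP libraries beside 2 input libraries. The design asks where in the genome NURF-1 was bound at this stage and how far the replicates share their sites. The replicate 1 list held 4856 peaks, 4850 of them nuclear, and the replicate 2 list 11771, 11765 of them nuclear. The mean was 8308 ± 4890 nuclear peaks (SD, n = 2). The whole-series list held 11796. Nuclear peaks covered 1.61 Mb (1.60% of the 100.3 Mb between chromosome ends) in replicate 1, 5.44 Mb (5.43%) in replicate 2 and 5.47 Mb (5.45%) in the whole-series list. Replicate 2 thus had 2.43 times as many nuclear peaks as replicate 1 and 3.39 times as many bases in them. Median peak width was 268.5 bp in replicate 1 and 351 bp in replicate 2, and the narrowest peak was 146 bp wide in every list. Across peaks, wider peaks scored higher (Spearman's rho 0.69 in replicate 1 and 0.81 in replicate 2).

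Nearly all sites of the shorter list were also sites of the longer one. Of the 4850 nuclear peaks of replicate 1, 4372 overlapped a replicate 2 peak (90.1%, 95% interval 89.3 to 91.0), against a mean of 9.69% in circular shifts. In the other direction, 4094 of 11765 nuclear replicate 2 peaks overlapped replicate 1 (34.8%, 33.9 to 35.7), against 3.95% by chance. Bases in both lists made up 25.2% of the bases in either, against 1.36% by chance. Each value exceeded all 10000 shifts (permutation test, one-sided p = 1e-04, the smallest they can give). Merging gave 12210 regions. Of these, 4061 were found in both replicates, 478 in replicate 1 alone and 7671 in replicate 2 alone. Regions in both replicates had a median width of 686 bp, those in replicate 1 alone 213.5 bp and those in replicate 2 alone 262 bp. Regions in both join peaks of 2 lists, which can only widen them. The shared peaks themselves had a median width of 273 bp in replicate 1 and 678 bp in replicate 2. The extents of shared peaks differed: 1650 pairs, 34.0% of replicate 1 peaks, overlapped by at least 50% of both peaks. With the 4850 best-scored peaks of each list, 77.4% of those of replicate 1 and 71.5% of those of replicate 2 were shared.

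The strongest sites were the shared ones. In replicate 2, the 4094 shared peaks had a median score of 88.95 and the 7671 others 8.75. In replicate 1, the medians were 11.92 for shared and 4.34 for unshared peaks. Both differences passed a permutation test over peaks (two-sided, 100000 resamples, p = 1e-05 each, the smallest possible). Within each of 3 groups of peak width, shared peaks also scored higher in each list, with differences from 1.71 to 18.2 in replicate 1 and from 4.21 to 81.62 in replicate 2. In the best-scored 10% of replicate 2, 96.5% of 1177 peaks were found in replicate 1 (95.3 to 97.4). In the lowest 10%, 3.40% were (2.51 to 4.59). For replicate 1, all 485 peaks of the best-scored 10% and all 485 of the next 10% were found in replicate 2, and 67.0% of the lowest 10% were (62.7 to 71.0). Across the 4372 shared replicate 1 peaks, scores in the 2 lists were correlated (Spearman's rho = 0.59, Pearson's r = 0.60, permutation p = 1e-05 each, adjusted p = 1e-05 over both relations). Peaks are not independent replicates.

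**Figure D1:**
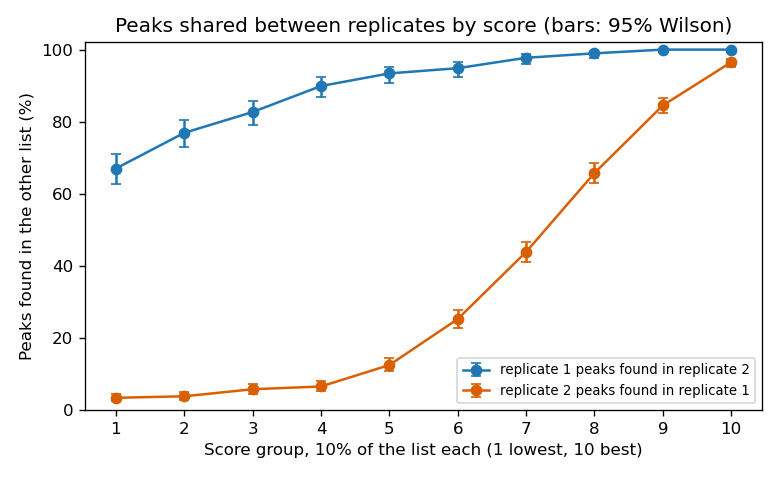
Share of nuclear peaks found in the other replicate (vertical axis, percent) by score group (horizontal axis, 10 groups of 10% of the list each, 1 lowest and 10 best), with 95% Wilson intervals as bars. Replicate 2 peaks (orange) go from 3.40% to 96.5%, and replicate 1 peaks (blue) from 67.0% to 100%.

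The 20 regions in both replicates with the best mean score rank lay on chromosome IV (7 regions), III (6), I (3), II (3) and V (1), and none lay on X. The first was chromosome III, 1618367 to 1619914 (1548 bp), with a score of 449.81 in replicate 1 and 373.73 in replicate 2, the best score in each list. A score of 373.73 in replicate 2 was shared by the region at III, 7854347 to 7855321 (975 bp), which scored 376.53 in replicate 1. Next came III, 3867019 to 3868198, which scored 414.70 and 363.13 in replicates 1 and 2. The region at IV, 4749365 to 4750491, scored 359.61 and 364.98. Another at IV, 654173 to 655546, scored 344.63 and 354.96. On chromosome II, the best-ranked regions were 8560704 to 8561686 and 8569053 to 8570021. On chromosome I, they were 7020665 to 7022091 and 14468704 to 14469799. The single region on V spanned 18533353 to 18534262. The 20 regions were 910 to 1548 bp wide, and each overlapped a peak of the whole-series list.

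Regions in 1 replicate alone ranked lower. The best-scored region of replicate 1 alone was II, 396457 to 396711, with a score of 26.78. It was followed by V, 17384322 to 17385297 (25.49) and X, 9185906 to 9186421 (24.91). The best-scored regions of replicate 2 alone were X, 7232168 to 7233060 (251.9), V, 9191429 to 9191807 (240.12) and I, 4490200 to 4490898 (212.84). These 3 ranked 306, 367.5 and 541 among the 11732 replicate 2 regions. All 6 regions were in the whole-series list.

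The whole-series list resembled that of replicate 2. It overlapped 94.7% of replicate 2 peaks (94.3 to 95.1) and 94.0% of replicate 1 peaks (93.3 to 94.6). Of its own 11781 nuclear peaks, 94.5% overlapped replicate 2 and 36.0% replicate 1. All 4061 regions found in both replicates were in it, as were 7048 of the 7671 in replicate 2 alone (91.9%, 91.2 to 92.5) and 185 of the 478 in replicate 1 alone (38.7%, 34.4 to 43.1). A further 452 of its peaks (3.84%) overlapped neither replicate list, with a median score of 3.67 against 19.07 for its other peaks. Of its peaks, 407 had the same first and last base as a replicate 2 peak and 0 as a replicate 1 peak. How the authors combined the replicates is not given in the sources used here.

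Chromosomes III and I carried the most NURF-1 regions per length and X the fewest. Regions in both replicates numbered 58.5 per Mb on III, 57.1 on I, 42.3 on II, 40.8 on IV, 29.7 on V and 23.1 on X. The X value was 0.51 times the autosomal mean of 45.7 ± 12.1 per Mb (SD, n = 5 autosomes). An exact permutation test gave a two-sided p = 0.167, the smallest that 6 chromosomes allow. The replicate 1 list gave 28.1 per Mb on X against 54.4 ± 13.5 on autosomes, a ratio of 0.52. The replicate 2 list gave 88.6 against 127.2 ± 30.3, a ratio of 0.70, and there V was the lowest chromosome at 87.5 per Mb (exact p = 0.667). X was furthest below the autosomes among the best-scored peaks, with no steady trend over the other score groups. For the score groups, the density of X was divided by that of the 5 autosomes pooled, not by the mean of their densities as above. In replicate 2 this density ratio was 0.87 in the lowest-scored 20% of peaks (exact 95% interval 0.77 to 0.97) and 0.48 in the best-scored 20% (0.41 to 0.55). The groups between had ratios of 0.77, 0.69 and 0.81, from the lower-scored up. In replicate 1 it was 0.59 (0.48 to 0.72) in the lowest-scored 20% and 0.25 (0.19 to 0.34) in the best-scored one, with 0.76, 0.64 and 0.45 between.

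**Figure D2:**
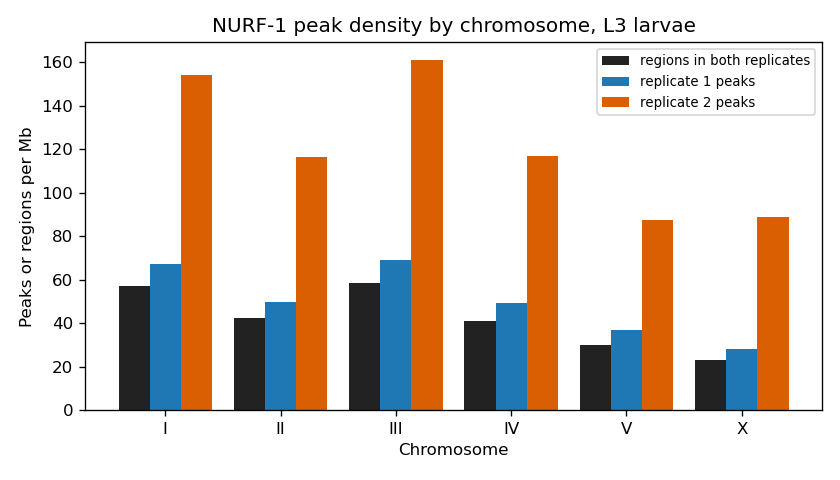
Peaks or regions per Mb (vertical axis) on each chromosome (horizontal axis) for regions in both replicates (black), replicate 1 peaks (blue) and replicate 2 peaks (orange). X has the lowest black and blue bars, at 23.1 and 28.1 per Mb, and V the lowest orange bar, at 87.5.

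Replicate 2 peaks on X were found in replicate 1 less often than autosomal ones. Of all 1570 X peaks, 421 were found (26.8%, 24.7 to 29.1), against 36.0% of all autosomal peaks. Given the scores of the X peaks, 30.2% would have been found without an X difference (permutation within 50 score strata, two-sided p = 3e-05). X and autosomal peaks were also compared within 5 score groups of replicate 2 peaks, without further matching of score. In the best-scored 20%, the found share was 84.5% for the lower-scored 10% of the list and 96.5% for the best 10%. Lower X scores inside a group may thus add to a difference there. X and autosomal peaks differed past the test in the best-scored 2 of the 5 groups (Fisher's exact test, two-sided). In the best-scored 20%, 77.6% of X peaks and 91.8% of autosomal peaks were found in replicate 1 (adjusted p = 6.74e-09 by Fisher's exact test). In the next 20%, 48.7% and 55.9% were (adjusted p = 0.0353 by Fisher's exact test). In the other 3 groups, 2.98% of X and 3.73% of autosomal peaks, 6.61% and 6.09%, and 16.2% and 19.3% were found, from the lowest-scored up (adjusted p = 0.683, 0.712 and 0.395 by Fisher's exact test). For replicate 1 peaks, 86.5% of 498 X peaks were found in replicate 2, against 87.8% given their scores (permutation p = 0.34). Of their 5 score groups, the second best passed the test, with 93.0% of X and 98.9% of autosomal peaks found (adjusted p = 0.00792 by Fisher's exact test). These tests treat peaks as independent, and the Fisher tests of either list do not match scores within a group. Without regard to score, V was as low as X in replicate 1: 86.1% of its 769 peaks were found (83.5 to 88.4), against 90.9 to 92.9% on I to IV.

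The middle 33.3% of the chromosome held 39.9% of regions in both replicates on V, 39.4% on II, 39.3% on III, 39.0% on I and 35.9% on IV, all above the share of an even spread. On X it held 25.6%. The mean over 6 chromosomes was 36.5 ± 5.53% (SD, n = 6), and its excess of 3.18 percentage points did not pass the test (exact sign-flip test, two-sided p = 0.219). With X left out, a choice made after its value was seen, the 5 autosomes had a mean excess of 5.36 ± 1.61 percentage points (SD, exact p = 0.0625, the smallest that 5 chromosomes allow). In each replicate list, X was also the only chromosome below 33.3%, at 26.3% in replicate 1 and 31.8% in replicate 2. Gene content along the chromosomes was not analysed here.

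The peaks of each replicate list lay close together more often than chance placement gives. For regions in both replicates, placement within windows could not decide this, since overlaps among placed regions raise the chance share. A neighbouring region within 1 kb was present for 16.7% of regions in both replicates, against 14.4% for random placement on the chromosome (permutation test, one-sided p = 0.001) and 16.0% for placement within windows of 100 kb (permutation p = 0.19). In the replicate 1 list the share was 27.5%, above the highest of the placements within windows at 17.8%. In the replicate 2 list it was 43.1%, above the highest at 34.8% (permutation p = 1e-04 each, the smallest possible). The 4372 shared replicate 1 peaks fell in 4061 regions, so some regions held more than 1 of them. Close peaks may thus be parts of 1 site, which was not tested. The median gap between neighbouring regions in both replicates was 12.5 kb. Of 999 windows of 100 kb, 65 held no region found in both replicates and 9 held no replicate 2 peak. The most regions in both replicates in such a window was 15, reached at IV, 2600001 to 2700000 and IV, 4700001 to 4800000, windows chosen after their values were seen. Across windows, the peak counts of the 2 replicates were correlated (Spearman's rho 0.66, Pearson's r 0.63); windows are not independent replicates.

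**Figure D3:**
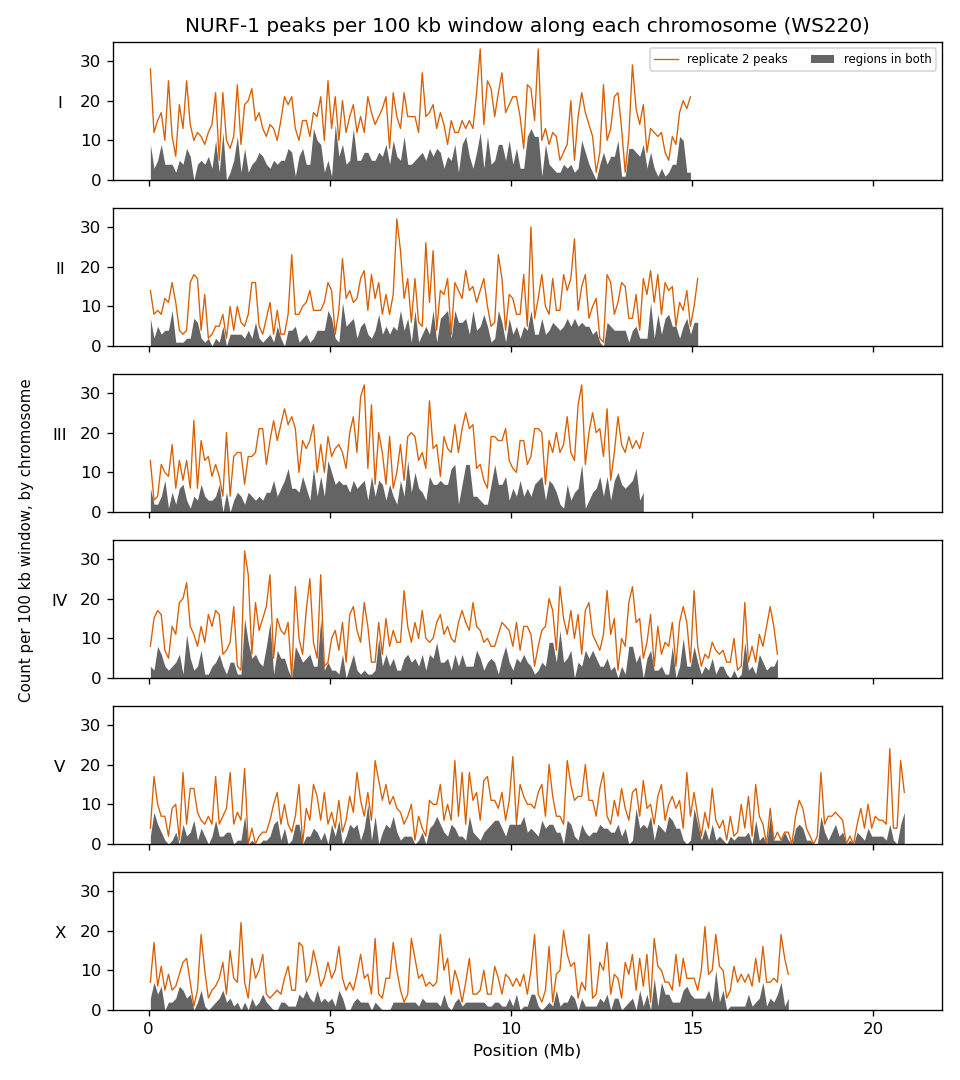
Number of replicate 2 peaks (orange line) and of regions in both replicates (grey area) per 100 kb window (vertical axes) along the 6 nuclear chromosomes in Mb (horizontal axis, WS220). Regions in both replicates reach 15 per window on IV, and 65 of the 999 windows hold none.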

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

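The tests in this part were chosen after the result was seen, except the comparison of the replicate overlap with circular shifts, which was set before the data were examined and whose bound was written once the overlap itself, but not the shifts, had been seen. Peaks on mitochondrial DNA lay outside the comparisons above and were noted because each list held more than 3. That cutoff marks what to note and is not an expected number of mitochondrial peaks. Without input values, binding there cannot be told apart from background. The replicate 1 list held 6 mitochondrial peaks, the replicate 2 list 6 and the whole-series list 15. The best-scored one spanned mitochondrial positions 12847 to 13741 in replicate 1 (score 81.45), 13381 to 13750 in replicate 2 (40.49) and 12756 to 13764 in the whole-series list (83.39). No other mitochondrial peak scored above 12.1 in replicate 1, 7.2 in replicate 2 or 18.73 in the whole-series list.

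The replicate 1 list was much shorter than that of replicate 2. Chance overlap with many wide replicate 2 peaks is argued against as the source of the sharing: 90.1% of replicate 1 peaks were shared, above the highest of the shifts at 25.6%. This does not bear on the difference in list length. A lower sensitivity of the replicate 1 call is a candidate explanation, since 96.5% of the best-scored 10% of replicate 2 peaks were found in replicate 1 and 3.40% of the lowest 10%. Replicate 1 lacks 41 peaks of that best 10%, and replicate 2 peaks on X were found less often than their scores give. Whether a lower sensitivity covers these was not tested. The design names no biological difference between the replicates, so no biological explanation was tested.

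X carried fewer regions per Mb than the autosomal mean. The loss of weak X peaks at the detection limit stays open. The ratio of X to autosomal density was 0.48 in the best-scored 20% of replicate 2 peaks and 0.87 in the lowest-scored 20%, but a lower X signal overall would move X peaks out of the best-scored group and below the limit alike. Lower X coverage in every library cannot be told apart from weaker binding. X peaks had a lower median score than autosomal peaks (13.15 against 17.33 in replicate 2), and input values were not analysed here. No biological explanation was tested.

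In all 3 lists, a peak began at the first base of each of the 6 nuclear chromosomes. Right ends were not tested, since chromosome lengths were taken from the last peak. That peak ended at the same base in all 3 lists on each of the 6 chromosomes, so the pattern may not be limited to left ends. Chance placement is argued against, since 6 left ends with a peak within 1 kb exceed the upper binomial bound of 3. Repeats collapsed in the genome assembly could give the same peaks, and cannot be told apart from binding without input values. The left end peaks had a median score percentile of 89.9 in replicate 1, 63.9 in replicate 2 and 68.7 in the whole-series list.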

How the results depend on the processing

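Of the 47 alternatives over 14 results, 35 were set before the data were examined and 12 were chosen after seeing the data. In 36 of them the test could fall on either side of 0.05, and 34 kept the direction and the side of the reported value. One exception was the spacing of regions in both replicates, where 16.7% had a neighbour within 1 kb: placement within windows of 100 kb, which keeps broad density, gave 16.0% by chance (permutation p = 0.19). Overlaps among placed regions raise that chance share, so this alternative cannot decide. The other was the share of replicate 1 X peaks found in replicate 2, which differed from expectation by -1.22 percentage points at like score (permutation p = 0.34), by -2.08 with width matched as well (permutation p = 0.1), and by -3.60 without matching (permutation p = 0.0053), which leaves the lower scores of X peaks in the difference. The alternatives for replicate overlap and for scores of shared and unshared peaks all gave the smallest p-value their permutation tests allow. Their p-values thus could not separate one setting from another. Overlaps of at least 50% were set against chance shares counted at 1 bp, and random placement leaves the observed share unchanged. All 4 shares for the whole-series list, which have no test, stayed within their intervals. The ratio of X to autosomal density stayed below 1 in all 6 alternatives and ranged from 0.36 for the better-scored 50% of regions to 0.70 without replicate 1, and was 0.68 in the whole-series list. Exact p-values for the density and centre comparisons stayed above 0.05, which the density test cannot pass. The mean excess of regions in the middle 33.3% ranged from 2.17 percentage points without replicate 2 to 5.36 on autosomes alone. Leaving out peaks at chromosome ends and those over 3 kb wide gave 89.9% of replicate 1 peaks shared. Overlap with a replicate left out has no value with 2 lists. No paired analysis was possible because only the ChIP samples have values, and the replicate numbers pair them with input libraries that were not analysed here. Other promoter windows, gene list settings and peak summits were foreseen but not run, since no annotation on WS220 was used and the lists give no summit. Sequencing depth is unknown, so a peak missing from a list shows only that it was not called there.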

Other observations

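The widest peak of each list lay near the right end of chromosome I, at 15060278 to 15071348 in replicate 1 (11071 bp), 15060300 to 15071355 in replicate 2 (11056 bp) and 15060260 to 15071378 in the whole-series list (11119 bp). Its scores were 38.0, 32.48 and 62.47, above those of 85.4%, 62.3% and 73.7% of the nuclear peaks of each list. The worm's large ribosomal DNA array is known to lie at that chromosome end; whether the peak covers it was not tested. The next widest peak was also in all 3 lists, at V, 7916845 to 7925051 in replicate 1 (8207 bp) and 7916870 to 7925043 in replicate 2 (8174 bp). The third widest of the whole-series list spanned V, 17119946 to 17126644 (6699 bp, score 128.35). These peaks were chosen after their values were seen.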
